A study of Caenorhabditis elegans with 2 samples.

How the data were processed

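The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) on whole Caenorhabditis elegans, a nematode. Per the labels, the strain carried an edited ekl-4 gene on chromosome I whose product bears a TY1, EGFP and FLAG tag, and an antibody against GFP was used. EKL-4 is the worm relative of DMAP1, a subunit of chromatin complexes of the NuA4/TIP60 and SWR1 type. Animals were young adults collected at 65 h after release from starvation as first-stage larvae, and chromatin was sheared by sonication to fragments of 200 to 800 bp. The labels give 2 biological replicates of 1 group, so no comparison between conditions was made.

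Per the accompanying text files, the authors called peaks on the ce11 genome build against a control alignment and ranked them by the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks repeat between libraries. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal value of each peak is the strength their caller gave it relative to the control. Its scale is not stated, so it was used to rank and describe peaks within a list. The deposited score of each peak is the authors' IDR score, which reaches 1000. The deposited q column holds −log10 of a q-value and was used in 1 alternative for the agreement between replicates. Each thresholded list holds only ranked peaks with a score of at least 830, and leaves some of those out. Per the accompanying text files, a further input that they do not describe entered the thresholded lists. There were 4 thresholded and 4 ranked lists, with 1 of each kind for replicate 1 and for replicate 2. Another pair ranked the peaks of the replicates against each other (the conservative list), and the last was larger. The conservative list was the main list. The ranking behind it also has 8 columns of values for single libraries, which were not used. Read depth is not known from these files, so no value is set against the number of reads. The control libraries were not analysed here.

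Coordinates are on ce11, whose chromosome lengths are those of WBcel235, and no deposited peak ended beyond them. Genes were taken from the Ensembl 115 annotation of WBcel235, with 19973 protein-coding genes on the nuclear chromosomes. Positions are 1-based. A gene was counted as having a summit where a peak summit lay within 500 bp of the 5' end of any of its transcripts. A summit can count for more than 1 gene. Mitochondrial peaks were left out of the tests.

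The tests, the 21 gene lists, the 14 motifs, the rule for naming genes and most alternatives were fixed before the data were examined. Overlap between replicates and the share of summits at gene starts were set against 1000 placements of the peaks at random within each chromosome. The smallest p these can give is 0.000999 one-sided (overlap) and 0.002 two-sided (gene starts). Gene groups were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists, over the RNA gene classes and over the motifs. Motifs were counted in the 201 bp around each summit, with controls at the same distance from the starts of genes that had no summit in any thresholded list, matched on GC content. The side of the gene start was tested by an exact sign test, and GC content by a permutation test with 100000 resamples. Intervals on shares are 95% Wilson intervals, and a share of 0 is given with the limit of 3 counts. Both cover counting error over genes or peaks only. Genes and peaks are not biological replicates, so the p-values describe these lists and not the spread between animals. A first look at the RNA gene classes also covered 3 classes outside the plan. The planned 7 were kept, and the wider set is given as an alternative.

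Named genes are ekl-4, the protein-coding genes within 500 bp of the 12 strongest main summits, and, for each list that passed and for the first 3 lists, the 3 members with the strongest summit and up to 2 without one. Each RNA gene class that passed adds its 2 strongest members. Of the listed names, 6 had no gene of that name in the annotation. Repeated sequence was measured as the percentage of 31-mers in a 201 bp window that occur more than once in the genome. Its cut of 10% was chosen after seeing the data.

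The procedures were tested on simulated data. With random genes, drawn independently of each other, in place of those with a summit, 0 of 420 list tests over 19973 genes were called. That check does not cover the linkage of genes that share a summit. All 21 lists were recovered when 50% of their members were given a summit. With 20% of members, 138 of 420 runs recovered the list, and 2 of 280 for lists of under 40 members, with no other list planted. Control windows set against other control windows gave 0 calls among 14 motifs over 1065 windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were the larger list, the summits at or above the median signal, each replicate's own list, other windows and distances, other backgrounds and controls, merged peaks, and, chosen after seeing the data, lists without summits in repeated sequence or on the shoulder of a stronger summit.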

Results

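Binding of the tagged EKL-4 protein was mapped in young adult worms in 2 biological replicates. The thresholded list of replicate 1 held 1495 peaks and that of replicate 2 held 1846, a ratio of 1.23. The conservative list held 2482 peaks, covering 818 kb or 0.816% of the nuclear genome, and the larger list held 2847. Peaks were mostly of a fixed width, with a median of 360 bp in the conservative list. There were no other conditions, so the questions below are how far the replicates shared peaks and where in the genome the summits lay.

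Most peaks of replicate 1 were also found in replicate 2, and among nuclear thresholded peaks the strongest site was the same in both. Of the 1495 peaks of replicate 1, 1046 (interval 67.6 to 72.2%) overlapped a peak of replicate 2 by at least 1 bp, and of the 1830 nuclear peaks of replicate 2, 1026 (56.1%, interval 53.8 to 58.3) overlapped one of replicate 1. Random placement gave a mean of 16.9 overlaps for the peaks of replicate 1, and at most 32 in either direction (permutation p = 0.000999 for each, one-sided, the smallest that 1000 placements can give). The main peak at tasp-1 (a threonine aspartase gene) had a signal of 605 in replicate 1 and 671 in replicate 2, and that at rpl-3 had 534 and 636. Over 1018 pairs of peaks within 200 bp, Spearman's rho of the signal was 0.662 and Pearson's r of its log2 was 0.60. With ranks from the authors' q column, rho was 0.408. Each replicate 1 peak was paired with its nearest replicate 2 peak, so 48 of the pairs reuse a replicate 2 peak, and rho was 0.697 over the 970 pairs left when each peak is used 1 time. These are correlations across peaks, which are not independent replicates. Of the main peaks, 1022 (41.2%) met a thresholded peak of both replicates, with a median signal of 160. A further 720 (29.0%) met a thresholded peak of neither, with a median signal of 84.8. In the ranked lists, which are much longer (49388 and 90719 peaks), 2461 main peaks met a peak of replicate 1 and 2463 met one of replicate 2.

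**Figure D1:**
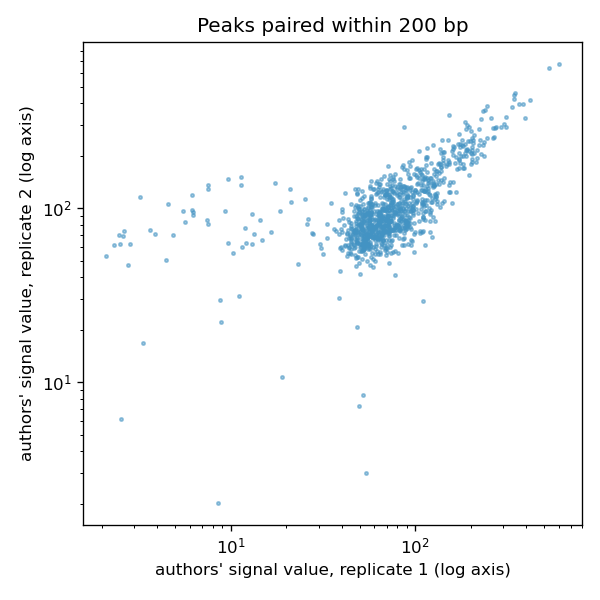
Authors' signal value of each peak in replicate 1 (x, log axis) against its partner in replicate 2 (y, log axis) for 1018 pairs with summits within 200 bp. Most pairs rise together (Spearman's rho 0.662), and low values, under 20 (a limit chosen after seeing the pairs), are in replicate 1 in 48 pairs and in replicate 2 in 7, or 14 and 7 with each peak used 1 time.

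The strongest sites of the main list lay upstream of tasp-1, of ribosomal protein genes and between a pair of HSP70-type genes. The highest signal in that list, 1259, was at chromosome III 10759091 to 10759441, with an intergenic summit at -39 bp from the start of tasp-1 (negative distances are upstream). The next, 1175, was at III 3867425 to 3867721, with an intergenic summit at -280 bp from the ribosomal protein gene rpl-3. Next in rank was II 11759290 to 11759698 (signal 835), between the divergent HSP70-type genes F44E5.4 and F44E5.5. It was followed by sites at -158 bp from cdc-48.1 (signal 799, II 10563453 to 10563707), which encodes an AAA ATPase that acts on ubiquitinated proteins, and at -416 bp from rpl-35 (signal 783, III 7854566 to 7854833). The remaining named genes at the 12 strongest summits were rpl-20 with Y17G9B.5 (756), set-16 with drr-2 (731), rpl-15 with K11H12.8 (715), mog-4 (652) and wwp-1 (641), all with intergenic summits. Of these 12 summits, 2 had no protein-coding 5' end within 500 bp.

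Summits were concentrated at annotated gene starts, on their upstream side. Where transcription begins was not measured. Of the 2482 main summits, 1152 (46.4%, interval 44.5 to 48.4) lay within 500 bp of a protein-coding 5' end, against 23.1% ± 0.851 (SD over 1000 random placements; permutation p = 0.002, two-sided, the smallest they can give). Of the 1330 summits away from gene starts, coding exons held 13.2% against 23.6% of such summits at random, and introns 25.9% against 35.4%. Intergenic sequence held 53.7% against 37.3%, and 3' UTRs 7.07% against 3.43% (permutation p = 0.002 for each of the 4, two-sided, a comparison added after seeing the data). As a share of all 2482 main summits, intergenic sequence showed no excess, 28.8% against 28.7% (permutation p = 0.963, two-sided). On that scale 3' UTRs held 3.79% against 2.64% (permutation p = 0.004, two-sided), and coding exons and introns stayed below random. The median summit at a gene start lay upstream, at -116.5 bp (quartiles -249.5 and 26), and 820 summits were upstream against 330 downstream (71.3%, interval 68.6 to 73.8, exact sign test p = 1.32e-48). The share at gene starts was 31.0% with a window of 250 bp and 62.5% with 1000 bp.

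**Figure D2:**
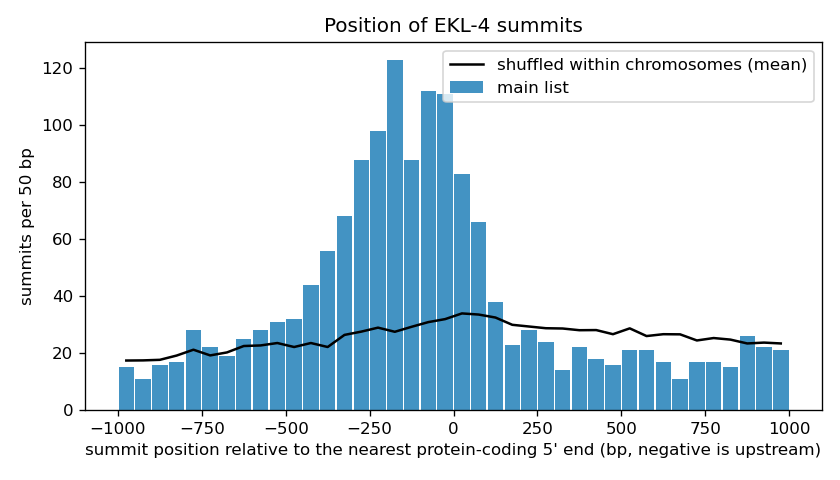
Number of main summits per 50 bp (bars) by distance in bp to the nearest protein-coding 5' end, negative upstream, with the mean of random placements within chromosomes (line). Bars exceed the line mainly upstream of the gene start, where the median summit sits at -116.5 bp.

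At the tagged gene itself, a peak had its summit in intergenic sequence upstream of ekl-4 (WBGene00013676, chromosome I 14469500 to 14476894, plus strand). It spanned I 14469173 to 14469532, reaching into the start of the gene, with a summit at -147 bp from the gene and a main signal of 234, which ranked 214 in the list. The signal there was 102 in replicate 1 and 139 in replicate 2. The same summit lay at -250 bp from the ribosomal protein gene rps-20. Within 2000 bp of ekl-4 there were 2 thresholded peaks in replicate 1 and 3 in each of replicate 2, the conservative list and the larger list.

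Of 19973 protein-coding genes, 1282 (6.42%, interval 6.09 to 6.77) had a main summit, and genes on the X chromosome had one less often. On X, 73 of 2731 genes (2.67%) had a summit against 1209 of 17242 (7.01%) on the autosomes (odds ratio 0.364, interval 0.283 to 0.463, Fisher's exact p = 2.88e-21). Among autosomes the share ran from 4.33% on V to 9.81% on III. Counting all main summits, at gene starts or not, X held 16.9 per Mb, against 18.2 on V and 35.0 on III. Genes in the central of 3 equal parts of an autosome had a summit more often, 8.13% against 6.32% in the arms (odds ratio 1.31, interval 1.16 to 1.48, Fisher's exact p = 8.3e-06). In the list of replicate 1 alone that odds ratio was 1.08 (Fisher's exact p = 0.313), and for X it was 0.234 there and 0.206 among summits at or above the median signal.

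Genes whose 5' end lay within 1000 bp of that of an opposite-strand gene (head to head) had summits most often among the gene arrangements tested. The rule did not check which way the pair faced, so not every such pair need share an upstream region. Of 3738 genes in head to head position, 515 (13.8%) had a summit against 4.72% of the rest (odds ratio 3.22, interval 2.86 to 3.63, Fisher's exact p = 8.67e-77). Because 1 summit between divergent genes counts for both, this share is partly set by the counting. Operon-like spacing was a 5' end within 500 bp downstream of the 3' end of a same-strand gene, whether or not the genes form an operon. Of 3618 such genes, 321 (8.87%) had a summit against 5.88% (odds ratio 1.56, interval 1.36 to 1.78, Fisher's exact p = 1.6e-10). With a window of 250 bp that odds ratio was 2.35.

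Cytosolic ribosomal protein genes and the oocyte and maternal list had summits far more often than other genes. Among cytosolic ribosomal protein genes 45 of 81 (55.6%, interval 44.7 to 65.9) had a summit against 6.22% of other genes (odds ratio 18.8, interval 11.8 to 30.2, Fisher's exact test with Benjamini-Hochberg adjusted p = 2.98e-31). The strongest were rpl-3, rpl-35 and rpl-20, while rla-0 and rla-2 had none. Of these 45 genes, 37 had the summit upstream and 22 shared it with another gene. Among oocyte and maternal genes 13 of 22 (59.1%) had a summit (odds ratio 21.3, interval 8.39 to 56.5, Fisher's exact adjusted p = 5.97e-10). These included cpg-1, for an eggshell proteoglycan (signal 339), puf-11, for an RNA-binding protein (173), and pos-1, for a maternal zinc finger protein (169), but not egg-2 or egg-3. The ribosomal odds ratio was 4.98 with a window of 250 bp and 51.4 with 1000 bp. The oocyte odds ratio was 9.4 in the list of replicate 2 alone and 10.1 in that of replicate 1 alone.

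Genes of EKL-4's own kind of complex and of the synMuv and DREAM regulators were also over-represented. Of the NuA4/TIP60 and SWR1-type complex genes 6 of 13 had a summit (46.2%, odds ratio 12.5, interval 3.48 to 43.7, Fisher's exact adjusted p = 0.00024). The strongest were epc-1 (signal 394, at -225 bp), htz-1, which encodes the histone variant H2A.Z (signal 254, at -302 bp, nearer to wapl-1), and ekl-4 itself, while arp-6 and gfl-1 had none. Of these 6 genes, 5 shared the summit with another gene, and 4 had it in the thresholded lists of both replicates. The odds ratio was 7.91 when each summit was given only to its nearest gene start. Of the synMuv and DREAM genes, which repress vulval and germline programmes, 9 of 25 had a summit (36.0%, odds ratio 8.25, interval 3.21 to 19.9, Fisher's exact adjusted p = 6.03e-05), led by lin-53 (473), lin-54 (436, a summit nearer to the ribosomal protein gene rpl-12) and lin-9 (353), with none at dpl-1 or hda-1. Of the Ras-ERK pathway genes 2 of 21 had one, cnk-1 (472) and egl-17 (153), and the list was not called (Fisher's exact adjusted p = 0.46).

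Stress response, splicing, proteasome and respiratory chain genes were also called higher. Stress response genes had summits in 9 of 25 cases (36.0%, odds ratio 8.25), led by the chaperone genes hsp-90 (signal 453, in its intron and nearer to C47E8.4), hsp-110 (425) and hsp-1 (372), with none at daf-16 or dve-1. Splicing factor genes had 10 of 33 (30.3%, odds ratio 6.38), led by snr-4 (394) and by rsp-1 and rsp-2, which share a summit (263). Proteasome genes had 9 of 33 (27.3%, odds ratio 5.5), led by rpn-3 (425, the same summit as hsp-110). Respiratory chain genes had 11 of 46 (23.9%, odds ratio 4.61), led by cox-5A (552), cox-5B (394) and atp-1 (312). Fisher's exact adjusted p ran from 6.03e-05 for stress response to 0.000396 for the proteasome. With each summit given only to its nearest gene start the splicing odds ratio was 3.96. Without genes in operon-like spacing the proteasome list was not called (odds ratio 3.06, Fisher's exact adjusted p = 0.0932).

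Histone, replication, and germline and meiosis genes had shares under 20%. Histone genes had 11 of 72 (15.3%, odds ratio 2.64, Fisher's exact adjusted p = 0.0114), led by his-67 and his-68, which share a summit (257), and his-37 (251). DNA replication and cell cycle genes had 7 of 43 (16.3%, odds ratio 2.84, Fisher's exact adjusted p = 0.0302), led by pcn-1, the sliding clamp gene (438), rfc-4 (246) and mcm-4 (153, a summit in its 3' UTR that counts through a transcript starting late in the gene). Germline and meiosis genes had 7 of 39 (17.9%, odds ratio 3.2, Fisher's exact adjusted p = 0.0195), led by the synaptonemal complex gene syp-4 (168, nearer to H27M09.5), the cohesin gene rec-8 (121, shared with mex-5) and syp-3 (111). The calls were lost in 3 of 11 alternatives for histone genes and in 4 of 11 for replication genes (largest Fisher's exact adjusted p = 0.143). For histone genes the odds ratio turned to 0.712 without summits in repeated sequence, with all 72 genes still counted. The germline list lost its call in 7 of 11, and was called neither in the list of replicate 1 alone (odds ratio 1.16) nor in that of replicate 2 alone (1.67).

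Chemoreceptor and collagen genes had summits less often than other genes. Of 1277 chemoreceptor genes 7 had one (0.548%, odds ratio 0.0753, interval 0.0302 to 0.156, Fisher's exact adjusted p = 2.9e-27), the strongest at sri-5 (244), srh-269 (187) and srh-16 (170). Of 170 cuticle collagen genes 2 had one, col-85 and col-38, whose summit is nearer to rpl-5 (1.18%, odds ratio 0.172, interval 0.0207 to 0.633, Fisher's exact adjusted p = 0.00484). Collagens were not called in either replicate's own list (odds ratios 0.358 and 0.383). No muscle gene of 29 and no sperm gene of 55 had a summit, which allows a share of up to 10.3% and 5.45%, and neither list was called (Fisher's exact adjusted p = 0.339 and 0.0738). Sperm genes were called lower in the larger list (Fisher's exact adjusted p = 0.0455) and among genes with a gene-class name only (0.0402). Neuron genes had 1 of 31, intestine genes 2 of 19, dosage compensation genes 1 of 11, small RNA pathway genes 3 of 32 and aminoacyl-tRNA synthetase genes 4 of 32, none of them called. Simulated shares of 20% in lists under 40 members were called in only 2 of 280 runs. No other list was planted there, so the adjustment was stricter than in the data, where germline and meiosis genes were called at 7 of 39. The simulation therefore cannot give the power of these tests, and these lists are left open. Small RNA pathway genes were called higher in the larger list (odds ratio 2.98, Fisher's exact adjusted p = 0.0406).

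**Figure D3:**
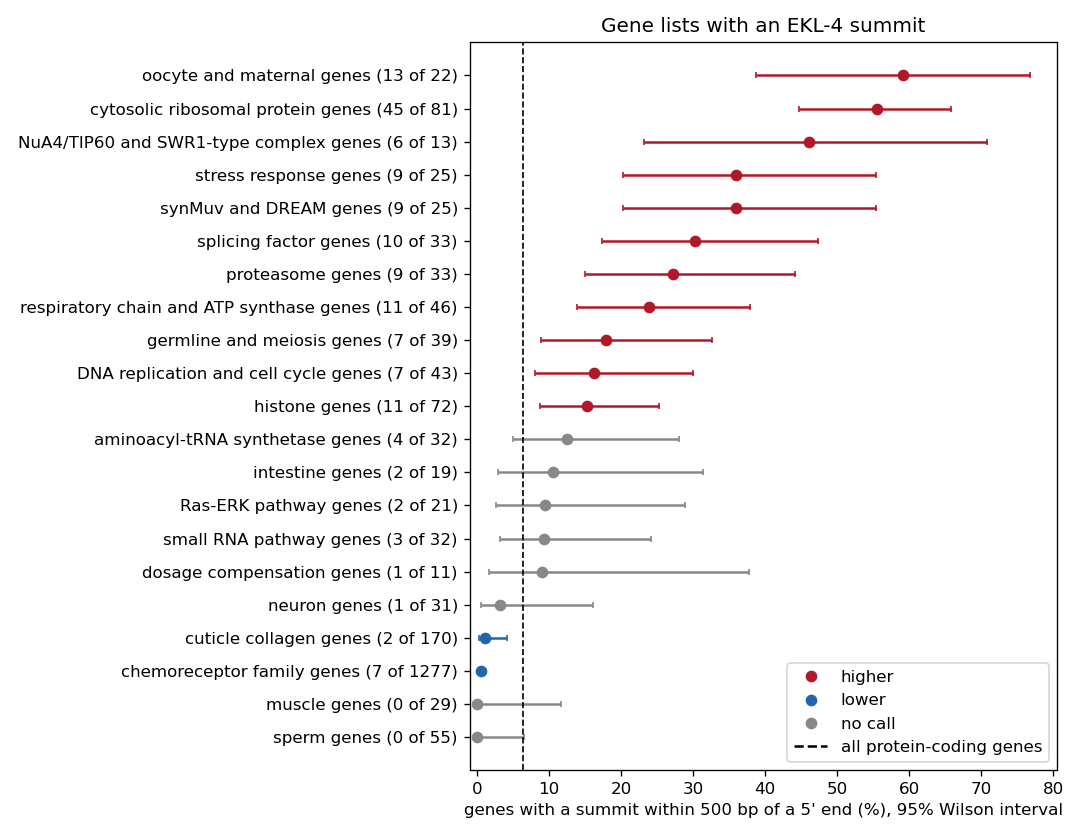
Percentage of each list's genes with a main summit within 500 bp of a 5' end (x), with 95% Wilson intervals, for the 21 lists (y). Colours give the call of Fisher's exact test after adjustment, and the dashed line marks all protein-coding genes (6.42%). Oocyte and ribosomal protein genes lie farthest to the right.

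Genes for tRNA, snRNA and snoRNA had summits more often than protein-coding genes. Of 612 tRNA genes 247 (40.4%, interval 36.5 to 44.3) had one, of 129 snRNA genes 55 (42.6%, interval 34.4 to 51.3) and of 346 snoRNA genes 103 (29.8%, interval 25.2 to 34.8). Against protein-coding genes the odds ratios were 9.86, 10.8 and 6.18 (Fisher's exact adjusted p = 3.62e-120, 1.08e-30 and 8.54e-39). Summits at tRNA genes sat on the gene, at a median of 20 bp downstream of its 5' end. The strongest tRNA members, WBGene00014333 and WBGene00014334, share a summit at X 9743654, in an intron of him-4 (signal 255). The strongest snoRNA genes were ZK994.7 (609, in an intron of pxn-1) and C51F7.3 (513, in an intron of frm-7). The strongest snRNA members, sls-2.1 (602) and sls-2.4 (516), belong to the SL2 spliced leader genes and lie in intergenic sequence. The piRNA genes had fewer, 70 of 15363 (0.456%, odds ratio 0.0667, Fisher's exact adjusted p = 3.04e-231), the strongest at 21ur-15381 (486) and 21ur-13751 (366). Most of these genes are closely packed, so they are not independent of each other. No call against protein-coding genes was made for miRNA (23 of 261), lincRNA (7 of 194) or rRNA genes (0 of 20, which allows up to 15%). Random placement gave miRNA genes a share of 2.5% ± 1.23 (SD over 100 placements), against 8.81% observed. For lincRNA genes it gave 2.45% ± 1.12 against 3.61%, and for rRNA genes 2.15% ± 3.04 against 0%. Without summits in repeated sequence the tRNA odds ratio turned to 0.905 (Fisher's exact adjusted p = 0.659) and that of snRNA genes fell to 2.49. All genes of each class were still counted there, multi-copy ones included. In the list of replicate 1 alone the tRNA odds ratio was 5.06. The miRNA class was called higher in each replicate's own list (odds ratios 1.84 and 1.87) and in the larger list (1.61).

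**Figure D4:**
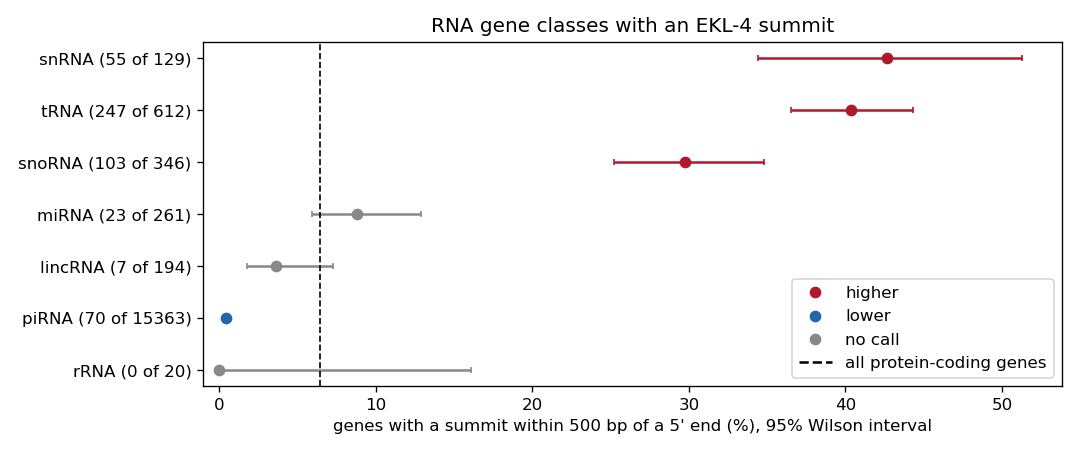
Percentage of the genes of each RNA class with a main summit within 500 bp of the 5' end (x), with 95% Wilson intervals, for 7 classes (y). The dashed line marks protein-coding genes (6.42%), and snRNA, tRNA and snoRNA genes lie to its right.

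Summit sequences at gene starts were rich in GC and in E2F sites. Mean GC was 42.7% ± 7.03 (SD, 1065 windows) against 34.9% ± 6.33 at the same distance from unbound gene starts, a difference of 7.8 percentage points (permutation p = 1e-05, the smallest that 100000 resamples can give). With GC matched, the E2F site (TTSSCGC) was in 21.8% of summit windows against 9.3% of controls (odds ratio 2.72, interval 2.1 to 3.54, Fisher's exact adjusted p = 1.92e-14). The CTGCGTCTC motif was in 7.61% against 3.1% (odds ratio 2.57, Fisher's exact adjusted p = 3.16e-05). Higher shares were also found for the GAGA repeat (10.4% against 6.48%), the heat shock element (2.72% against 1.03%), the CHR element (46.9% against 41.3%) and the B box of RNA polymerase III genes (2.63% against 0.469%), with Fisher's exact adjusted p from 0.000205 to 0.0227. The GATA site was less frequent, 10.4% against 17.2% (odds ratio 0.561, Fisher's exact adjusted p = 3.51e-05). The other 7 motifs were not called. Without summits in repeated sequence the calls of the B box (odds ratio 0.4996), the heat shock element (1.82) and the CHR element (1.25) were lost. That setting took repeated windows out of the summits but not out of the controls. Its odds ratios therefore do not compare like with like, and the B box value is no evidence of depletion. With shorter windows the calls of the GATA site (0.734), the GAGA repeat (1.35) and the heat shock element (3.28) were lost. Flanking windows as controls turned the CHR odds ratio to 0.928 and raised those of the CTGCGTCTC motif to 9.14, the GAGA repeat to 4.15 and the E2F site to 4.11. With these controls the SP1-like site was called higher (odds ratio 3.65, from 1 in the main test) and the splice acceptor lower (0.717), and the ETS core was called lower in 3 other alternatives (odds ratios 0.488 to 0.676). The heat shock element reached 6.33 in the larger list.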

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

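The tests of high expression and of tRNA genes alike in part were chosen after the result was seen. The others were written before their result, but the heat shock test uses a limit of 10% repeated 31-mers chosen after seeing the data. Mitochondrial peaks appeared in the list of replicate 2 (16 peaks, median signal 1124) and in the larger list (18 peaks, median signal 1160), and there were 0 in replicate 1 and in the conservative list. They were noted because the tests leave the mitochondrial genome out. The thresholded lists leave out peaks that reach the score of 830, namely 37 in replicate 1, 78 in replicate 2, 56 in the conservative list and 75 in the larger list. Of the 56 left out of the conservative list, 51 lie in windows with at least 10% repeated 31-mers, and the strongest, at X 15810926 to 15811285, has a signal of 1346, above every peak kept.

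Summits at tRNA genes may in part come from reads shared between tRNA genes, and these data do not settle it. A protein-coding start nearby is argued against, since 39.1% (interval 34.4 to 44.1) of the 386 tRNA genes with no such start within 1000 bp had a summit, against 6.42% of protein-coding genes. Of the 140 tRNA genes whose whole sequence occurs once, 31.4% (interval 24.3 to 39.5) had a summit, which met the bound set in advance against shared reads, but that bound was wrong because these genes still share a median of 42.6% of their 31-mers with other sequence. Of the 23 tRNA genes with under 10% repeated 31-mers 2 had a summit (8.7%, interval 2.42 to 26.8), too few to tell. Removing summits in repeated sequence ended the call, but all 612 tRNA genes were still counted. That loss was therefore largely set by the counting and cannot decide the question. Among genes with under 10% repeated 31-mers, 87 of 306 snoRNA genes (28.4%, interval 23.7 to 33.7) and 10 of 29 snRNA genes (34.5%, interval 19.9 to 52.7) had a summit. No biological explanation was tested.

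The heat shock element was more frequent at summits, and repeated sequence could account for part of this. Among all main summits, windows with at least 10% repeated 31-mers held it in 8.57% of cases and other windows in 2.04%. In flanking windows the shares were 3.99% and 1.24%. Within repeated windows, then, it was more frequent at summits (odds ratio 2.25, interval 1.32 to 3.93, Fisher's exact p = 0.0017). In windows under that limit it was also more frequent than in flanking windows (odds ratio 1.66, interval 1.07 to 2.56, Fisher's exact p = 0.0179). Limits of 1, 5 and 20% gave 1.75, 1.73 and 1.65, but with the same 40 summits that hold the element, so they add no further support. For all main summits, against flanking windows not matched on GC, repeated 31-mers are argued against as the whole cause by a narrow margin. The measure counts exact 31-mers only, so it does not cover repeats whose copies have diverged. The comparison with flanking windows does not decide the case of gene starts. There the GC-matched call was lost without summits in repeated sequence (odds ratio 1.82). Only the summit windows were filtered in that setting and the controls kept repeated windows, so the lost call cannot decide it either. The call at gene starts was lost in 4 of its 8 alternatives, so a biological reading remains a hypothesis.

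Ribosomal protein genes could have summits because they are highly expressed, which the files do not measure. Counting each summit only for its nearest gene start left 33 of 81 genes with one (odds ratio 12.6, interval 7.77 to 20.1), which argues against summits of neighbouring genes as the cause. Muscle and vitellogenin genes, abundant in their tissues, had summits in 2 of 35 cases. The upper bound of 18.6% was below the lower bound of 44.7% for ribosomal protein genes. None of the 29 muscle genes had a summit, so the 2 cases were vitellogenin genes. The pooled bound therefore does not hold for the few vitellogenin genes taken alone. Since no list limited to a somatic tissue was called higher in these whole animals, sites used in 1 tissue may be diluted, and high expression stays open. No biological explanation was tested.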

How the results depend on the processing

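The settings without repeated sequence, without shoulder summits with 3 more RNA classes and with each peak paired 1 time were chosen after seeing the data. Replicate overlap, the share at gene starts, the X chromosome, operon-like and head to head genes, summit position and GC content kept their direction and their side of the threshold in all alternatives run. The odds ratio of autosome centres against arms ran from 1.08 (without replicate 2, not called) to 1.41 over the replicates' own lists and the other settings. Rank agreement between replicates was 0.696 with summits within 100 bp, 0.697 with each peak paired 1 time and 0.408 by the q column. The cause of these shifts was not tested. The ribosomal, oocyte, NuA4, synMuv, stress response, splicing, respiratory chain and chemoreceptor lists kept their calls in every alternative run. So did snoRNA, snRNA and piRNA genes and the E2F and CTGCGTCTC motifs. Lists called lower numbered 1 in place of 2 among summits at or above the median signal and, without a replicate, 1 and 1, and 3 with the larger list and with gene-class names only, where sperm genes joined them. Calls of lists, RNA classes or motifs not made in the main test were gained 11 times, by sperm (2), small RNA (1) and miRNA genes (3), the ETS core (3), the SP1-like site (1) and the splice acceptor (1). Motifs called lower numbered 2 in place of 1 with the larger list and with flanking controls, and 1 to 2 without a replicate. Motifs called higher fell from 6 to 3 without repeated sequence. RNA classes called lower numbered 2 with 3 more classes tested, pseudogenes being added by construction.

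Called results that turned were histone genes (0.712), tRNA genes (0.905) and the B box (0.4996) without repeated sequence, and the CHR element (0.928) with flanking controls. The setting without repeated sequence by construction removes summits of multi-copy genes. It leaves those genes in the gene counts and repeated windows among the motif controls. Uncalled odds ratios that crossed 1 were intestine (0.716, larger list; 0, median signal), dosage compensation (0, median signal and without either replicate), neuron (1.38, without replicate 1), aminoacyl-tRNA synthetases (0.691 without replicate 2 but 1.34 without replicate 1; 0.801, no operon-like genes), small RNA (0.758, 250 bp; 0.572, nearest start), Ras-ERK (0, no repeats), E-box (0.928) and CRE (1.4) at median signal, T tract (0.806) and CRE (1.28) with flanking controls, and the splice acceptor (1.16, another seed). The B box without replicate 2 had no control window with the site and so no finite odds ratio. No setting without a replicate exists for the overlap or agreement of the replicates. No paired analysis was possible because there is 1 group. Depth is not known from these lists.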

Other observations

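In a search beyond the lists, 175 families of genes that share a name prefix and have at least 10 members were tested for summits in the main list after seeing the data. Fisher's exact test with Benjamini-Hochberg adjustment called 8 families higher and 6 lower, of which 5 and 3 have no member in the lists fixed in advance. The rest, such as rpl, rps and str, repeat those lists in whole or in part. The vha genes, for subunits of the vacuolar proton pump, had 8 of 20 members with a summit (odds ratio 9.77, interval 3.46 to 26.1, Fisher's exact adjusted p = 0.000774). The cyn genes, for cyclophilins, had 6 of 16 (odds ratio 8.78, Fisher's exact adjusted p = 0.00615), and the dnj genes, for DnaJ-type co-chaperones, 7 of 29 (odds ratio 4.66, Fisher's exact adjusted p = 0.0288). The vps genes, for vacuolar protein sorting, had 7 of 31 (odds ratio 4.27, Fisher's exact adjusted p = 0.0371). The kin genes, for protein kinases, had 6 of 23 (odds ratio 5.16, Fisher's exact adjusted p = 0.0364).

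Of the families called lower, 3 have no member in those lists. None of 170 fbxa genes, for F-box proteins, had a summit (Fisher's exact adjusted p = 0.000819). The clec genes, for C-type lectins, had 2 of 240 (Fisher's exact adjusted p = 0.000841) and the nhr genes, for nuclear hormone receptors, 4 of 269 (odds ratio 0.218, Fisher's exact adjusted p = 0.00481).

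Of the 1330 main summits more than 500 bp from a protein-coding 5' end, 275 (20.7%) were within 500 bp of the 5' end of a tRNA, snoRNA or snRNA gene. The other 1055 had no such gene start. Of all main summits 525 (21.2%) were in windows with at least 10% repeated 31-mers, against 15.2% ± 0.69 (SD over 100 random placements).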
